A study of Homo sapiens with 2 samples.

How the data were processed

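Total RNA of MKN-1 cells was profiled on Illumina human bead arrays with 47229 probes in the table, 1 array of a mock pool and 1 of an shHDAC2 pool. Per the labels' protocols, RNA came from 3 independent extractions per condition and was mixed in equal amounts, and the knockdown cells were stable G418-selected clones carrying an shRNA plasmid. The labels speak of more than 1 such clone and do not say which was put on the array. What the mock cells received, and whether they carried a control plasmid or hairpin, is not given in the sources used here.

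The deposited probe table holds non-normalized intensity on a linear scale, with a detection p-value per probe and array, per the file headers. The detection p-values deposited by the authors take steps of 1 in 770, and a probe is called detected here at a p-value under 0.01. Median signals lay close to the signal of probes with a detection p-value near the middle of its range, 100.1 on the mock array and 93.0 on the shHDAC2 array, so the deposited intensity was not background-subtracted. Scanner, software and any step before this table are not given in the sources used here, and the table holds no bead numbers or bead errors. The authors also deposited processed values, whose scale and normalization are not stated. Set against log2 of each array's intensity, the authors' values correlate at 0.9996 for mock and 0.9995 for shHDAC2, so they are taken as log2 levels, neither centred nor ratios. Both columns hold the same sorted values, as quantile normalization leaves them, and both have a median of 6.99. The distribution they were set to is not that of the mean of these arrays, and its origin is unknown.

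Intensities were background-corrected, quantile normalized and put on a log2 scale with neqc of limma 3.58.1 in R 4.3.3, which infers the background from the detection p-values (normexp, offset 16). Further steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9. By the platform annotation 30111 probes had 1 gene symbol, 8 had several and 17110 had none. Probes with several or none were left out of gene results. Symbols were updated through the gene identifier for 30072 probes and the transcript accession for 18 and kept for 21, using RefSeq names of the GRCh38.p14 assembly. No coordinate of that assembly is given, since the files name no build. The 20037 symbols on the array gave 10894 genes with a probe detected on at least 1 array, of which 10441 were detected on both, 138 on the mock array only and 315 on the shHDAC2 array only. A gene's value is that of its detected probe with the highest mean signal. Of 2779 genes with more than 1 detected probe, 1358 had probes of opposite sign, which is stated where such a gene is named.

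With 1 array per group no test was run. Genes were counted at a log2 difference of at least 1 in size. For a gene detected on 1 array only, the fold is a lower bound, the bright array's log2 value minus the higher of the gene's own value and the lowest detected value on the other array (6.26 on mock, 6.17 on shHDAC2). Such a bound holds for the background-corrected scale only, since ratios of the deposited signals, which still hold the background, are smaller. It does not allow for measurement noise. The SD of the log2 differences was 0.298 in the 1090 dimmest genes, so a log2 bound smaller than that shows no direction. The 29 gene lists were each summarized by the median difference of members detected on at least 1 array, with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. This percentile treats genes as independent and describes these arrays only. Some listed genes had no probe matched to their symbol and were not analysed here. The internal spread comes from 2603 pairs of probes of 1 gene detected on both arrays. The SD of the difference within a pair was 0.212, or 0.150 for 1 probe, the log2 differences of the paired probes correlated at 0.178, and 55.9% of pairs had the same sign.

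The groups, the lists, the rule for named genes and the alternatives were fixed before the data were examined, unless stated otherwise. Named were all detected histone deacetylases and INK4 and CIP/KIP inhibitors, and the 12 genes with the largest positive and the 12 with the largest negative difference among genes detected on both arrays whose detected probes all share a sign, leaving out provisional symbols. Genes detected on 1 array only were to be named, up to 5 in each direction, if their bound was 2-fold or more, and none was. In each list up to 4 detected members with the largest differences were named. The alternatives were no background correction, median scaling, cyclic loess, the authors' deposited values, an offset of 50, detection at a p-value under 0.05, on both arrays, or no detection filter, the mean of a gene's detected probes, thresholds of 1.5-fold and 3-fold, and list means. A limit to genes with a mean log2 signal of 8 or more, a second interferon list, a list of antigen presentation and interferon gamma genes, a second squamous list and a list of interferon ligands were chosen after seeing the data.

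The steps were tested on a simulated mock and shHDAC2 pair of 11348 genes. Of 50 genes seeded 3-fold higher 100.0% were called at least 2-fold higher, and of 50 seeded 3-fold lower 98.0% were called lower. Of 11118 unchanged genes 0 were called, but their simulated differences had an SD of 0.130, against 0.179 for all genes on the real arrays, so this 0 does not carry over to the data. A list of 30 genes seeded at 1.25-fold reached percentile 100, and an unchanged list 46.1. Both simulated arrays were built from the mock array's signal with independent noise per probe. The recovered shares and list percentiles therefore apply to that setting only.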

Results

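MKN-1 is an established human gastric cancer cell line. Whole-genome expression was measured on 2 Illumina bead arrays, 1 of a pool of mock RNA and 1 of a pool of RNA from cells stably transfected with a plasmid that expresses a short hairpin RNA against HDAC2 (shHDAC2). Each pool mixed equal amounts of RNA from 3 extractions, so each group had 1 array and no difference below has a replicate check, an error or a p-value. The median signal was 125.9 on the mock array, where 17224 of 47229 probes (36.5%) were detected. It was 118.6 on the shHDAC2 array, with 17683 probes (37.4%) detected. Values are normalized log2 signals, differences are shHDAC2 minus mock, and having only 1 array per group limits their precision. By its title and design, the study asks what loss of HDAC2, a class I histone deacetylase, does to p16INK4a expression, survival and growth of gastric cancer cells.

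HDAC2 itself was lower in the shHDAC2 pool, at 46.7% of the mock level. Its normalized log2 signal was 12.33 in mock and 11.23 in shHDAC2, a difference of -1.10, and its signal before normalization was 5482 and 2374. Among genes detected on both arrays this was the largest decrease, and it was 8.51 times the SD of the differences of genes of similar brightness. A second HDAC2 probe was at background on both arrays (detection p-values 0.507 and 0.410) and carries no information. HDAC1, the closest paralog of HDAC2, differed by 0.08, and HDAC3 by -0.20. Of 18 histone deacetylase and sirtuin genes on the array, 15 were detected, 7 with a difference above 0 and 8 below. HDAC2 was the only member lower by at least 1.5-fold, and none was higher by that much. The list's median difference was -0.04, at percentile 25 among random gene lists of the same size and expression. SIRT6 (0.36) and HDAC11 (-0.20) had the next largest differences on both arrays. Both had low signals and stood at 0.16 and -0.08 in the authors' deposited values, where HDAC3 stood at -0.20. HDAC9 was detected on the shHDAC2 array only, with a bound of 1.03-fold that lies inside the spread of dim genes. The remaining members HDAC4, HDAC6, HDAC7, HDAC8, SIRT1, SIRT2, SIRT4, SIRT5 and SIRT7 differed by -0.04, 0.00, -0.10, 0.03, 0.07, -0.04, 0.18, -0.11 and -0.06. The 3 detected SIRT5 probes did not share a sign. Of 28 subunits of the Sin3, NuRD and CoREST complexes, through which HDAC1 and HDAC2 act on chromatin, 25 were detected with a median of 0.04 (percentile 90.5). The methyl-DNA binding protein MBD2 was higher by 0.41, MTA1 by 0.23 and SIN3B by 0.20. The remodeller CHD3, at a low signal, was lower, at -0.38 here and -0.16 in the authors' deposited values. After median scaling, which put the median of all genes at -0.04, this list's median was -0.02.

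CDKN2A, the locus of p16INK4a, differed little between the pools. Its brightest probe, assigned to the p16INK4a reference transcript in the platform table, read 10.29 in mock and 10.39 in shHDAC2, a difference of 0.10 or 1.07-fold. That is 0.738 times the SD of the differences of genes of similar brightness. A second detected probe, assigned to the p14ARF transcript of the same locus, differed by 0.08, and the remaining probe was below detection on both arrays. The probe sequences were not used to check that these probes separate the transcripts, which share exons. Among the other inhibitors of cyclin-dependent kinases, CDKN1C (p57) differed by -0.29 and CDKN2B (p15INK4b) by -0.19. CDKN1A (p21) differed by -0.05, CDKN1B (p27) by -0.03 and CDKN2D (p19INK4d) by -0.01, these 3 within the SD of 1 probe (0.150). A second CDKN1B probe of similar signal, detected on both arrays, differed by -0.16, just beyond that SD. All 6 INK4 and CIP/KIP genes on the array were detected, with a median of -0.04 (percentile 27.6). CDKN2C was not analysed here.

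Cell cycle genes stood close to 0 as groups. The G1 cyclins, their kinases, the RB family and the E2F factors (18 of 19 detected) had a median of -0.005, at percentile 45.9. RBL2 (p130) differed by -0.23, CDC25A by 0.23 and E2F3 by -0.17. CCND2, detected on the shHDAC2 array only, had a bound of 1.17-fold, inside the spread of dim genes. For CDC25A the detected probes had opposite signs. Among 28 detected genes of S phase and DNA replication the median was 0.05 (percentile 95.5), with 17 above 0 and 11 below. The licensing factor CDC6, at a low signal, was lower, at -0.56 here and -0.26 in the authors' deposited values. POLE2 was lower, at -0.19, while TYMS was higher by 0.22 and MCM2 by 0.18. All 30 genes of the G2/M and mitosis list were detected, with a median of 0.01 (percentile 73.2). In that list CENPE differed by 0.35, BUB1 by -0.22, CENPF by 0.20 and MKI67, the Ki-67 antigen, by 0.15. After median scaling the S phase and G2/M medians were -0.001 and -0.03, both above the median of all genes (-0.04).

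Apoptosis genes also stood close to 0 as groups. The p53 targets (19 of 24 detected) had a median of -0.05 at percentile 15.7, with RRM2B (-0.33) and MDM2 (-0.31) lower and GADD45A (0.22) higher. RRM2B and MDM2 had low signals and stood at -0.20 and -0.13 in the authors' deposited values. Of 23 pro-apoptotic genes, 21 were detected, with a median of 0.05 (percentile 87.9). APAF1, the scaffold of the apoptosome, differed by 0.48, HRK by 0.31 and the TRAIL receptor TNFRSF10B by 0.24. CASP8 was detected on the shHDAC2 array only, with a bound of 1.02-fold, inside the spread of dim genes. The 14 detected anti-apoptotic genes had a median of -0.01 (percentile 45.3). BCL2, which blocks mitochondrial apoptosis, was lower by at least 1.5-fold at a low signal, with a difference of -0.68 here and -0.28 in the authors' deposited values. BAG4 (0.29), BAG1 (-0.20) and BIRC6 (0.20) followed, and the BAG4 probes had opposite signs. Autophagy genes were lower as a group, with 18 of 28 detected members below 0 and a median of -0.09 (percentile 0.73). The largest differences belonged to ATG14 (-0.36), UVRAG (-0.27), PIK3C3 (-0.25) and the cargo receptor SQSTM1 (-0.23). UVRAG had a probe of opposite sign, and with the mean of a gene's detected probes the percentile of the autophagy median was 3.84.

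Few genes differed by 2-fold or more. Of 10894 genes detected on at least 1 array, 2 were at least 2-fold higher and 4 at least 2-fold lower, and on both arrays the counts were 1 and 2. IFI44L, an interferon-induced gene, was 2.33-fold higher (log2 difference 1.22). HDAC2 and MZT2A, a subunit of gamma-tubulin complexes, were lower, MZT2A with a difference of -1.09. The other 3, named after their values were seen, were detected on 1 array only and have lower bounds under 2-fold on the background-corrected scale. They are ESCO1 (at least 1.46-fold higher), the small Cajal body RNA SCARNA27 (at least 1.55-fold lower) and S100A7A (at least 1.86-fold lower). At a threshold of 1.5-fold, 16 genes detected on both arrays were higher and 32 lower, but among the 7543 genes with a mean log2 signal of 8 or more the counts were 7 and 7. Across genes, which are not independent replicates, the arrays correlated with Pearson's r of 0.996 and Spearman's rho of 0.996. The SD of the log2 differences ranged from 0.298 in the 1090 dimmest genes to 0.122 in the 1090 brightest, so a given difference weighs less in a dim gene.

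**Figure D1:**
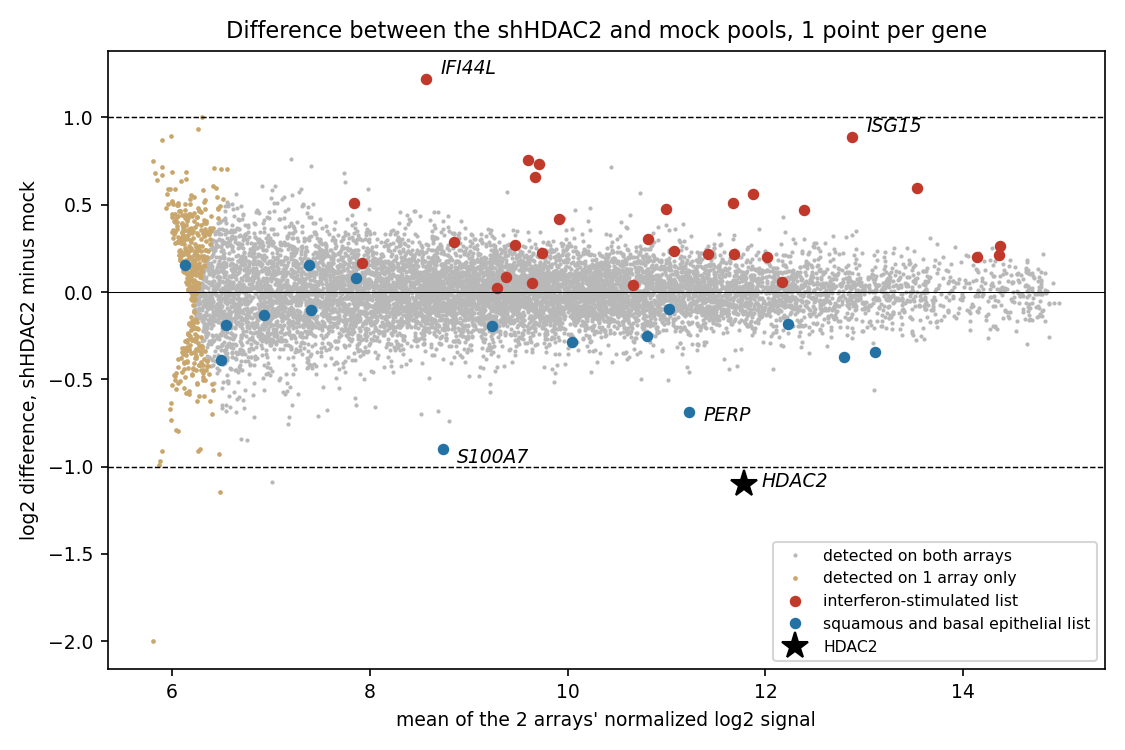
Log2 difference between the shHDAC2 and mock arrays (vertical axis) against the mean normalized log2 signal of both arrays (horizontal axis), 1 point per gene, with dashed lines at 2-fold. The spread narrows as signal grows, HDAC2 lies at -1.10 at a high signal, and the 29 interferon-stimulated genes (red) all lie above 0, 27 of them after median scaling.

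The genes with the largest positive differences on both arrays were, in order, IFI44L, ISG15 (0.89), ARRDC4 (0.76), OAS1 (0.76), IFIT1 (0.73), EPSTI1 (0.72), MNS1 (0.68), XAF1 (0.66), KLHL17 (0.63), RALGAPA2 (0.61), MX1 (0.60) and NRAV (0.59). ISG15 is a ubiquitin-like protein, OAS1 makes the activator of RNase L, and MX1 is an antiviral GTPase, all of them induced by interferon. On the negative side, HDAC2 and MZT2A were followed by S100A7 (-0.90), FAM114A1 (-0.85), AKR1B15 (-0.84), GPR37L1 (-0.76), LIPG (-0.74), MIR635 (-0.72), CROT (-0.72), TXNDC15 (-0.71), OAZ2 (-0.70) and PPIF (-0.69). S100A7 (psoriasin) is an antimicrobial protein of keratinocytes, LIPG is endothelial lipase, CROT a peroxisomal carnitine acyltransferase and PPIF the mitochondrial cyclophilin. S100A7 and AKR1B15 have close paralogs, S100A7A and AKR1B10, whose transcripts their probes may share. In the authors' deposited values all 24 kept their sign, but 10 of them, all with a mean log2 signal under 8, had differences smaller by more than 1.5 times. The same held for 37 of the 146 genes named by the fixed rule, each with a mean log2 signal under 8. None of the 146 had the opposite sign there. Neither this nor the kept sign of the 24 is a separate check of direction. Both ways of processing keep each array's probe order and give both arrays the same distribution, which fixes the sign of a probe's difference. Genes named outside that rule were not counted. MZT2A, for example, stood at -0.58 and FAM114A1 at -0.40, against 1.01 for IFI44L and -1.07 for HDAC2.

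Interferon-stimulated genes were higher in the shHDAC2 pool as a group. All 29 detected members had a difference above 0 (27 of 29 after median scaling), where 49.5% of all analysed genes did. Their median was 0.27, above that of every one of 10000 random lists. In this list 6 members were at least 1.5-fold higher, IFI44L (2.33-fold), ISG15 (1.85-fold), OAS1 (1.69-fold), IFIT1 (1.66-fold), XAF1 (1.58-fold) and MX1 (1.51-fold). The same 6 made up all but 1 of the 7 genes that were at least 1.5-fold higher among genes with a mean log2 signal of 8 or more. The seventh was EPSTI1, 1.64-fold higher. The list's median member was 1.21-fold higher.

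Squamous and basal epithelial genes were lower as a group. Of 16 detected members, 13 had a difference below 0, and the median of -0.19 stood at percentile 0.01. S100A7 differed by -0.90, PERP, a desmosome-associated target of p53 family proteins, by -0.69, KRT5 by -0.39 and the calprotectin subunit S100A9 by -0.37. KRT5 had a low signal and stood at -0.16 in the authors' deposited values, where S100A9 stood at -0.36. Simple epithelial genes (18 of 28 detected) had a median of -0.07 (percentile 5.70). CDH1, which encodes E-cadherin, differed by -0.47 (-0.31 in the authors' deposited values), ST14 by -0.29, TJP1 by -0.29 and CLDN7 by -0.20. The mesenchymal and EMT list (16 of 29 detected) had a median of -0.08 (percentile 4.05). In it TAGLN was higher by 0.40 and TCF4, at a low signal, by 0.30 (0.13 in the authors' deposited values). SNAI2 differed by -0.24 with probes of opposite sign, and ZEB2, detected on the mock array only, was at least 1.48-fold lower. Gastric and intestinal lineage genes were mostly undetected. The 5 detected gastric genes had a median of -0.10 (percentile 15.7), with GATA5 at -0.17, FOXA2 at -0.15 and TFF2 at -0.10, and GATA6 was detected on the shHDAC2 array only. The 4 detected intestinal genes, OLFM4 (-0.16), CDX2 (-0.13), ANPEP (-0.10) and MUC2 (-0.05), had a median of -0.11 (percentile 15.1).

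**Figure D2:**
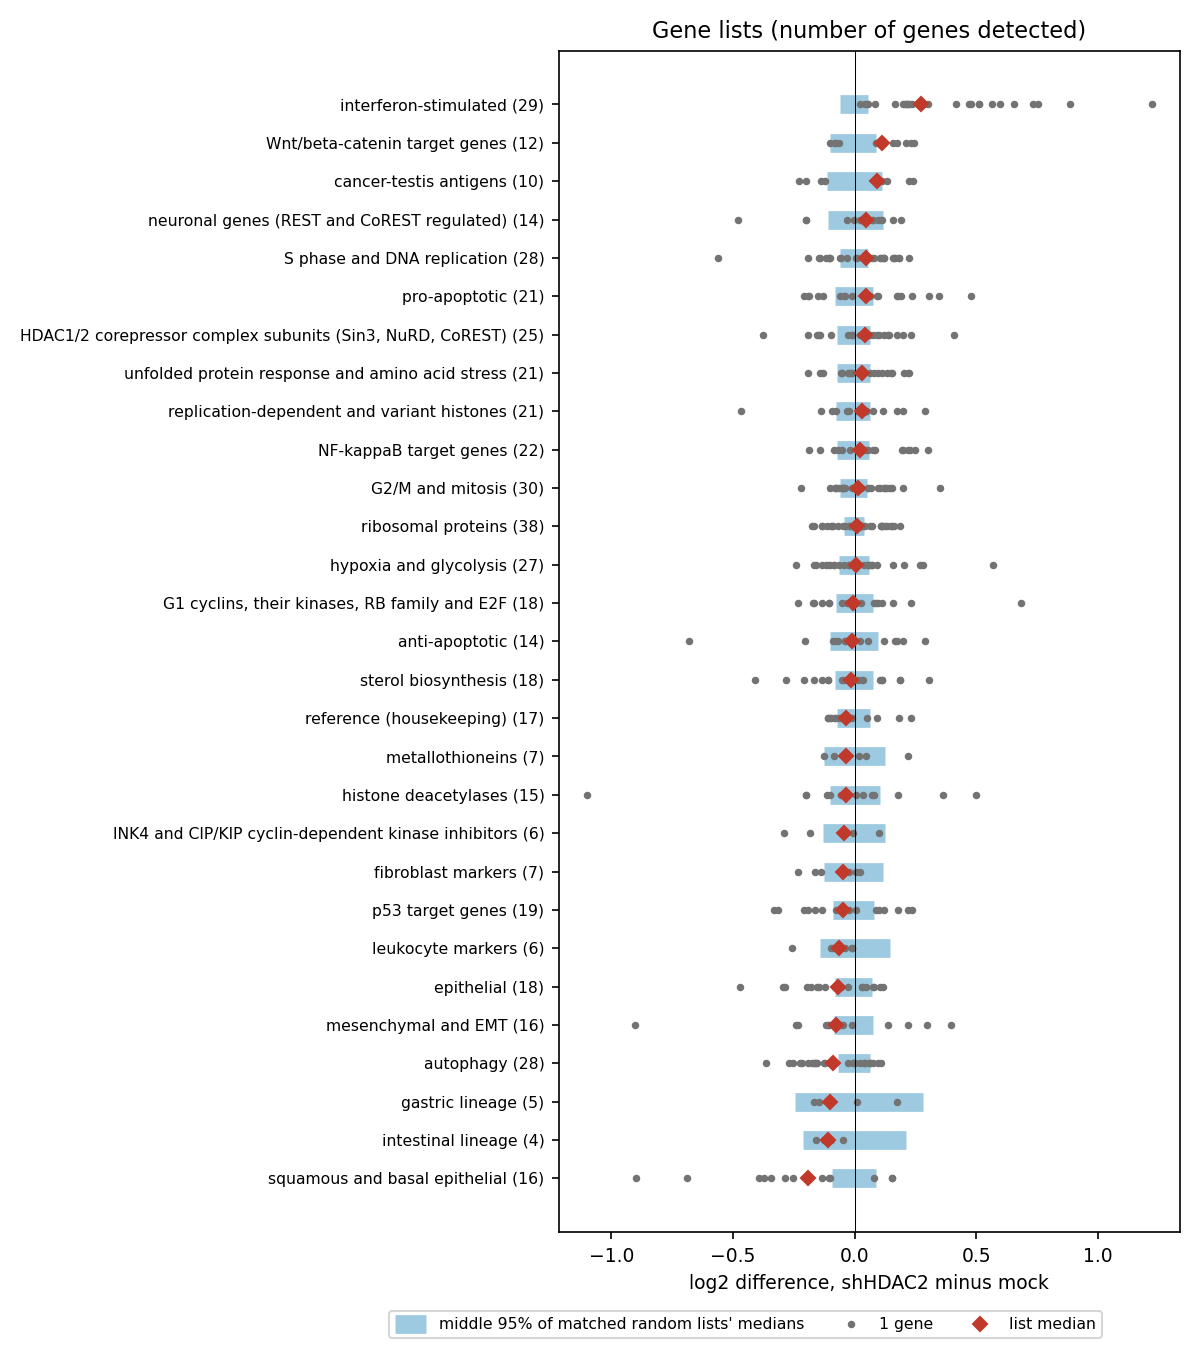
Log2 difference, shHDAC2 minus mock (horizontal axis), of the detected members of the 29 gene lists, with 1 grey point per gene, a red diamond at the list's median and a blue bar over the middle 95% of the medians of matched random lists. The interferon-stimulated and Wnt medians (0.27 and 0.11) lie above their bars, and the squamous and autophagy medians (-0.19 and -0.09) below theirs.

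Targets of Wnt/beta-catenin signalling had the next highest median, 0.11 over 12 detected genes, at percentile 99.1, with 8 above 0. BMP4 differed by 0.25, ZNRF3 by 0.23, MYC by 0.21 with probes of opposite sign, and SP5 by 0.17. With the mean of a gene's detected probes the percentile was 96.4, and among genes with a mean log2 signal of 8 or more it was 93.5, with 4 of 7 members above 0. Of the 29 lists, 2 lay above and 2 below the middle 95% of random lists, where chance alone would place 1.45. The medians of the remaining 25 ran from -0.11 to 0.09.

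Stress and metabolic lists were among those 25. The unfolded protein response and amino acid stress list (21 detected) had a median of 0.03 (percentile 85.2), with XBP1 (0.22), DDIT4 (0.22), ATF3 (0.20) and DNAJB9 (-0.19) farthest from 0. Hypoxia and glycolysis genes (27 detected) had a median of 0.01 (percentile 61.6). The glucose transporter SLC2A3 was higher by 0.57, HK2 by 0.28 and PFKFB4 by 0.27, and EGLN3 differed by -0.24. Sterol biosynthesis genes (18 detected) stood at -0.02 (percentile 38.7), led by MVD (-0.41), CYP51A1 (0.31), INSIG1 (-0.28) and ACAT2 (-0.21). The 7 detected metallothioneins had a median of -0.04 (percentile 31.2), led by MT1M (0.22), MT1E (-0.12), MT2A (-0.08) and MT1X (0.05). NF-kappaB targets (22 detected) had a median of 0.02 (percentile 78.6), and TNFAIP3 (0.30), CCL5 (0.25), NFKB2 (0.23) and IER3 (0.22) differed most. After median scaling the medians of the stress, hypoxia and NF-kappaB lists were -0.01, -0.02 and -0.01, all above the median of all genes (-0.04).

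Histone genes (21 detected) had a median of 0.03 (percentile 82.5, and -0.01 after median scaling). H3-3B was lower, at -0.47, and H2AC25 (0.29), H2BC21 (0.20) and H2AJ (0.17) were higher. Germline and neuronal genes, often silent outside their own tissues, did not stand apart. The 10 detected cancer-testis antigens had a median of 0.09 (percentile 94.7) but -0.02 with the mean of each gene's probes, with MAGEA3 at 0.24, MAGEA6 at -0.23, MAGEC1 at 0.23 and GAGE2A at -0.20. These families hold near-identical copies that a probe cannot separate, and the MAGEA6 and MAGEC1 probes had opposite signs. Neuronal genes (14 of 30 detected) had a median of 0.05 (percentile 77.2). VGF (-0.20), SYN1 (-0.20) and CHGA (0.19) differed most among those on both arrays. GAP43, detected on the mock array only, had a bound of 1.07-fold, inside the spread of dim genes.

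Lists that served as references stayed near 0. The 38 ribosomal protein genes had a median of 0.01 (percentile 70.2, and -0.03 after median scaling), with RPS18 (0.19), RPL37 (-0.17), RPL13 (-0.17) and RPL35 (0.16) farthest out. The 17 housekeeping genes had a median of -0.04 (percentile 17.3), with 13 below 0 and 4 above. GUSB (0.23), HPRT1 (0.18), YWHAZ (-0.11) and PPIA (-0.11) differed most. Probes of HPRT1 and of RPL13 had opposite signs. Markers of other cell types were few. Among fibroblast markers 7 of 20 were detected, with a median of -0.05 (percentile 23.7), led by S100A4 (-0.23), COL5A2 (-0.16), COL5A1 (-0.14) and FBLN1 (-0.05, with probes of opposite sign). Among leukocyte markers 6 of 24 were detected, all below 0, with a median of -0.06 (percentile 21.5), led by CD79B (-0.26), LCP1 (-0.10), ITGB2 (-0.09, with probes of opposite sign) and CD68 (-0.04).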

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

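Probes with no gene in the platform table were left out of the comparisons, and 4 of the 3697 detected ones were at least 2-fold higher on the shHDAC2 array, against 1 at least 2-fold lower. None of these 5 was detected on both arrays, so each fold is a lower bound, under 2-fold for all but ILMN_3303295. ILMN_1746972 was at least 1.32-fold higher and ILMN_3201523 at least 1.64-fold lower. ILMN_3240094 had a bound of 1.02-fold, inside the spread of dim genes. For ILMN_1706612 the bound showed no rise. The brightest by far was ILMN_3303295, at background on the mock array (detection p-value 0.039) and well above it on the shHDAC2 array, with signals of 141.2 and 587.9. Its normalized log2 value was 5.83 and 9.04, which is at least 6.91-fold higher on the background-corrected scale used here. Without background correction the fold is smaller, and the difference in the authors' deposited values was 2.01. That is a larger difference than that of any named gene, and the probe is unnamed here.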

How the results depend on the processing

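One alternative, the limit to genes with a mean log2 signal of 8 or more, was chosen after seeing the data. HDAC2 ranged from -1.18 to -1.07 over all settings. No value past 2-fold among the genes named by the fixed rule changed sign, nor did any list outside the middle 95%. ESCO1, SCARNA27 and S100A7A, named outside that rule, were not among the recomputed genes. Of 319 recomputed list medians or means 292 moved by less than the spread of random lists and 27 by more. Of 1390 values of the 145 other genes named by the fixed rule 1321 stayed within the spread of 1 probe and 69 did not. Array signal over background limits what can be read from dim genes, and the absence of a second array per group limits everything else.

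Median scaling put the median of all genes at -0.04, and with it the list medians were -0.074 for G1 genes, -0.035 for G2/M, -0.022 for corepressor subunits, -0.012 for NF-kappaB targets, -0.0013 for S phase, -0.123 for autophagy, -0.130 for epithelial genes, -0.024 for hypoxia and glycolysis, 0.234 for interferon-stimulated genes, -0.128 for mesenchymal genes, -0.088 for housekeeping genes, -0.0059 for histones, -0.027 for ribosomal proteins, -0.246 for squamous genes and -0.0084 for the unfolded protein response. The mean of members gave 0.010 for S phase, 0.021 for cancer-testis antigens and 0.374 for interferon-stimulated genes. With the mean of detected probes the medians were -0.018 for cancer-testis antigens, -0.106 for epithelial genes, 0.236 for interferon-stimulated genes and 0.081 for the unfolded protein response. Without a detection filter they were -0.057 for cancer-testis antigens, 0.031 for gastric genes and 0.041 for hypoxia and glycolysis. Cyclic loess gave 0.034 for ribosomal proteins, and genes with a mean log2 signal of 8 or more gave -0.2875 for squamous genes. Part of the difference under median scaling is common to all genes by construction, and apart from that the cause was not tested for these list values.

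Genes at least 2-fold higher, 2 in the report, numbered 37 at 1.5-fold and 0 at 3-fold, and 1 each with the authors' values, cyclic loess, detection on both arrays, a mean log2 signal of 8 or more, median scaling, no background correction and an offset of 50. Genes at least 2-fold lower, 4 in the report, numbered 50 at 1.5-fold and 1 at 3-fold, 2 each with the authors' values, detection on both arrays, no background correction and an offset of 50, and 1 with a mean log2 signal of 8 or more. The Wnt percentile of 99.1 was 96.4 with the mean of detected probes and 93.5 among genes with a mean log2 signal of 8 or more.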

Other observations

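The tests that use normalization, bright genes, second probes and the spread by signal were chosen after the results were seen, and the second lists were written after the first ones had been seen, leaving out genes whose values were known. Members of those lists are named after their values were seen. The list of antigen presentation and interferon gamma genes (25 detected) had a median of -0.05, at percentile 9.79, and did not stand apart from random lists. Its largest negative differences belonged to genes of MHC class II presentation, CD74, the invariant chain (-0.37), HLA-DMB (-0.31) and HLA-DRA (-0.30). Its largest positive difference was 0.33 for SOCS1, a feedback inhibitor of cytokine signalling.

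Interferon ligands were almost all undetected. Of 21 genes on the array 2 had a detected probe, IFNA21 on both arrays close to background (-0.19) and IFNL1 on the shHDAC2 array only. The IFNL1 probe had detection p-values of 0.0429 in mock and 0.0026 in shHDAC2, and a second IFNL1 probe was undetected on both. IFNB1 was undetected on both.

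The interferon-stimulated genes had the list median farthest from 0 of the 29 lists. The median nearest to 0 over 4 other normalizations and the authors' values was 0.2335, above all random lists. That argues against the choice among these settings as the cause. They rescale the same 2 arrays and treat genes of similar signal much alike, so nothing beyond that choice was tested. Only median scaling (0.2335) and cyclic loess (0.2787) could change a probe's sign, since the other settings keep the probe order of the main one. Noise near background is argued against, since 27 of the 29 detected members had a mean log2 signal of 8 or more. Their median was 0.2715, the same as for the full list and above all random lists of such genes. For 10 of these genes, single probes that bind other transcripts are argued against by the next brightest probes. Their median was 0.3749 with 8 above 0, PSMB9 (-0.50) and GBP1 (-0.01) being the exceptions. The other members, among them IFI44L, ISG15, IFIT1 and MX1, had no second probe detected on both arrays and were not tested this way. A second list of 31 detected interferon-induced genes had a median of 0.2146 with 27 above 0, among them TRIM22 (0.59), CMPK2 (0.53) and USP18 (0.50), so a wider interferon response may be present in this pool. Whether it follows loss of HDAC2, the introduction of an shRNA plasmid or differences between clones or arrays cannot be told apart. The number of arrays labelled as carrying a non-targeting shRNA is 0, and each group had 1 array.

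Squamous and basal genes were lower, and the same check argues against noise near background as the whole cause. The 9 members with a mean log2 signal of 8 or more, all below 0, had a median of -0.2875. The median nearest to 0 over the other normalizations and the authors' values was -0.1693. It came from the authors' values, which keep the probe order of the main setting. Only median scaling (-0.2457) and cyclic loess (-0.1957) could change a probe's sign. Each left 13 of 16 members below 0, though median scaling also put the median of all genes at -0.04. That argues against the choice between these settings and the main one as the whole cause. Nothing beyond that choice was tested for normalization. A second squamous list had a median of -0.1003 (25 detected, 16 below 0, percentile 0.35), with S100A14 (-0.67), KLK5 (-0.36) and SERPINB3 (-0.30) lowest, so a wider decrease may be a candidate explanation, weaker than in the first list. Probes shared by paralogs such as S100A7 and S100A7A were not tested. Differences between clones of the line stay open and cannot be told apart from the knockdown, since the largest number of arrays in a group is 1.

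Genes past 2-fold other than HDAC2 and IFI44L had a mean log2 signal under 8. ESCO1, SCARNA27 and S100A7A were detected on 1 array only, while MZT2A was detected on both, with signals of 277.8 in mock and 165.1 in shHDAC2. The SD of the differences in the 1090 dimmest genes was 2.4353 times that in the 1090 brightest, so measurement noise that grows as signal falls may account for part of the list of large differences. No biological explanation was tested for it.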
